A study of Mus musculus with 8 samples.

How the data were processed

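Two-colour Agilent microarrays measured total RNA of mouse mammary epithelial cells, 1 array for each of 8 samples in 4 groups of 2: MaSC-enriched and LP-enriched cells, each as control and with IFNα. Test RNA carried Cy5 and a universal mouse reference RNA, a mix of mouse cell lines, carried Cy3. The titles give both fractions the same surface phenotype text, and the groups were taken from the sample characteristics, which separate them. The labels do not state whether cells were sorted before or after the culture. Images were quantified with Agilent Feature Extraction 11.0, per the submitters' processing notes. The values deposited by the authors are log ratios of the channels, used here as log2. The log base is not stated and was taken as 2 because the values reach beyond what log10 of 16-bit signals allows, and the direction was taken as sample over reference from the dyes. If the base differed, all log2 values would scale by 1 factor and the tests would not change. How the ratios were normalized and centred, and why 347 of 55681 probes are empty on at least 1 array, is not stated. Array medians ran from -0.14 to 0.15. Probe intensities were not used here, so signal over background is not known for any value. Empty probes per array numbered 30 on LP control replicate 1 and 43 to 138 on the others.

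Of the probes 30626 carried 1 gene symbol in the probe annotation and 25055 carried none. The 30398 named probes with values on all arrays were averaged by symbol, which gave 21794 genes, 6730 of them from several probes. A further 99 genes had only probes with an empty array and were left out of the tests. No other normalization was applied. Groups were compared with limma 3.58.1 in R 4.3.3 by a model with 1 mean per group over all 8 arrays, without a replicate block, and moderated by empirical Bayes without trend or robust options (4 residual and 1.98 prior degrees of freedom). P-values are two-sided and adjusted by Benjamini and Hochberg within each comparison, and a gene passed below 0.05. The comparisons were IFNα against control in MaSC and in LP, the difference between these responses (MaSC minus LP), MaSC against LP in controls and with IFNα, and the average of both responses.

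Before the data were examined, 21 gene lists with 497 genes were fixed, of which 454 were tested. The others were not analysed here: 29 were not matched to a named probe, and 14, Krt18 among them, had only probes with an empty array. The lists covered interferon-stimulated genes, the interferon pathway, interferon-inducible GTPases and chemokines, MHC class I presentation, basal and stem-cell-enriched, luminal progenitor, whole-lineage luminal and mature luminal markers, milk and secretory genes, cell cycle, p53 and cell death, Wnt and Notch, epithelial-mesenchymal transition, early stress, hypoxia and glycolysis, cholesterol and lipid synthesis, ribosomal proteins, and markers of leukocytes, fibroblasts, endothelial and mural cells, and adipocytes and red cells. Each list with at least 5 measured genes was tested with limma's camera, two-sided, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. With the preset correlation 6, 10, 5, 8 and 10 lists were called in the MaSC response, the LP response, the difference, the control populations and the treated populations, and with an estimated correlation 2, 2, 0, 1 and 1. The lists were not tested in the average response. Lists that no paragraph names were not called. Counts of members "adjusted over the list alone" apply Benjamini and Hochberg within the list.

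Named genes followed a rule fixed at the same time. It took up to 5 genes with the largest rise and 5 with the largest fall among those that passed with all samples of a group on 1 side, or up to 3 of lowest p where fewer passed. It also took from each list up to 4 passing members with the largest change, or else the member with the lowest p, and always Irf7, Isg15, Ifit1, Mx1, Ifnar1, Ifnar2, Lcor, Krt5, Krt14, Trp63, Krt8, Elf5 and Kit. Gene-model names were passed over. Some values were named outside this rule after they were seen. Among them are Pecam1, Hbb-b1, Hba-a1 in the control populations, and Ifi27l2a and Trim30a in MaSC.

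The procedure was tested on simulated data of the size of the MaSC comparison. Of 50 genes shifted by each log2 change, 0% were recovered at 1, 50% at 2, 84% at 3 and 92% at 5, with 7 false among 120 calls, and 0 calls were made in a comparison with no change. Changes under about 2 on the log2 scale were therefore mostly out of reach for single genes. A list shifted by 0.5 was called by camera at adjusted p = 4.4e-09 and no unshifted list was. The simulated genes were drawn independently, with the same spread on all arrays, so this does not test lists of correlated genes. In the data the estimated correlation was 0.31 for interferon-stimulated genes, 0.65 for cell cycle genes and 0.88 for hypoxia and glycolysis genes.

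Alternatives were the replicate number as a block, quantile normalization, median centring, leaving out genes with a low mean value, the probe with the highest mean per gene, probes tested singly, trend and robust moderation, array weights, only the compared groups in the fit, genes with at least 1 value per group, a minimum log2 change of 1, each array left out in turn, and an estimated correlation for lists. Scaling every array to the same standard deviation, a list of cornified envelope genes and a test of unnamed probes were added after the data were seen. The closing section gives their effect.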

Results

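Gene expression was measured in mammary epithelial cells from virgin wild-type FVB/N-J mice. A fraction enriched for mammary stem cells (MaSC), the basal cells that can regrow a gland after transplantation, and a fraction enriched for luminal progenitors (LP), which give rise to the luminal lineages, were grown as mammospheres. Cultures received interferon-α (IFNα), a type I interferon, at 1000 U/ml or served as controls, and were harvested after 8 days. Each of the 4 groups held 2 samples, with 1 two-colour array per sample. Every value is a log2 ratio of the sample to a common mouse reference RNA, so 0 means equal signal in both. The 21794 genes tested had a gene symbol and a value on all 8 arrays. The values of LP control replicate 1 were narrower than those of the other arrays, with a standard deviation over probes of 0.63, where no other array was below 1.19. For that reason the count of genes past the threshold in each comparison is also given without this array, a choice made after its spread was seen. Where a comparison does not use a group, leaving out either array of that group must give the same result. Only the spread shared by all groups then changes. Results for IFNα in MaSC, or between treated populations, without LP control replicate 1 therefore say nothing about that array alone. Pairwise correlations between arrays, taken across all probes, ran from 0.54 to 0.82. Only 2 arrays per group limit the precision. The labels do not say whether samples of a group came from separate animals or cultures, so all p-values measure only the spread between these samples.

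**Figure D1:**
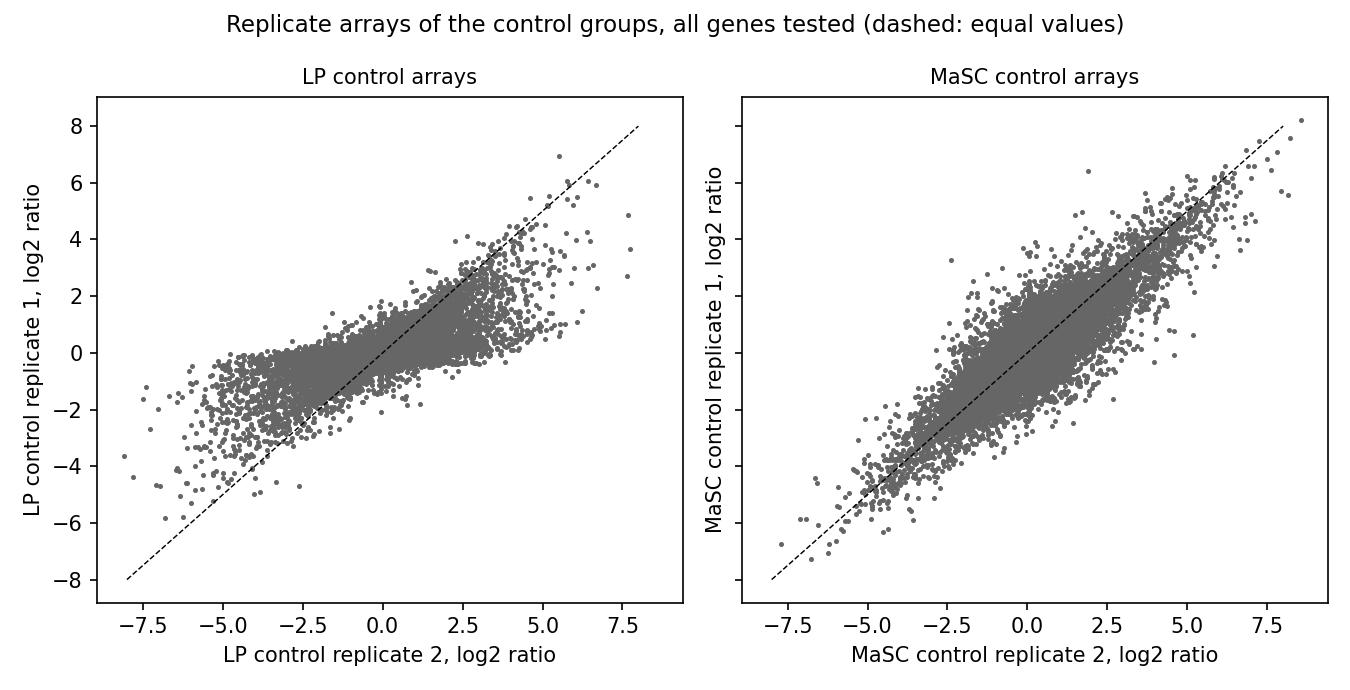
Log2 ratios of sample to reference for all 21794 genes in both replicate arrays of the LP control group (left) and of the MaSC control group (right), 1 point per gene, with a dashed line of equal values. LP control replicate 1 spans a narrower range than replicate 2, with a standard deviation over probes of 0.63, while the MaSC control arrays follow the line of equal values.

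The first comparison asked what IFNα did in MaSC cultures. With IFNα 50 genes rose, 25 of them from the list of interferon-stimulated genes, and 1 gene fell. Among genes that passed, the largest rises were in Oas1a, a sensor of double-stranded RNA, by 6.93 ± 0.42 (log2 change ± standard error, 2 samples against 2, limma adjusted p = 0.0075), in Gbp3, a guanylate-binding protein, by 6.62 ± 0.57 (adjusted p = 0.023), in the oligoadenylate synthetase-like gene Oasl2 by 6.62 ± 0.41 (adjusted p = 0.0075), in Usp18, which removes ISG15 from proteins and dampens receptor signalling, by 6.44 ± 0.40, and in Rtp4 by 6.20 ± 0.41. Olfr194, an olfactory receptor gene, fell by 2.44 ± 0.26 (adjusted p = 0.042, but 0.051 when the probe with the highest mean stood for each gene). Cela3b, at -1.62 (adjusted p = 0.081), and the serotonin receptor gene Htr1b, at -1.87 (adjusted p = 0.13), were the next lower genes by p and did not pass. The count of 51 genes depended on single arrays: it was 57 without either LP control array, 2 without either LP array with IFNα and 0 without any 1 of the MaSC arrays. Fitting the MaSC groups alone also gave 0. The genes called without either LP control array held only part of the 51.

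The interferon lists carried this response in MaSC. Of 53 measured interferon-stimulated genes 25 rose, and 51 did so when adjusted over the list alone, with a median log2 change of 3.21. The camera test, which compares a list with all other genes, gave adjusted p = 1.9e-127, and adjusted p = 0.020 with an estimated correlation. Of 26 genes for MHC class I presentation 4 rose (16 adjusted over the list alone), with a median of 1.49 (adjusted p = 8.4e-33, and adjusted p = 0.020 with an estimated correlation, or 0.078 without LP control replicate 1). They were B2m, the light chain of MHC class I, at 2.99 ± 0.17, the class I genes H2-T10 at 2.31 ± 0.22 and H2-Q10 at 1.75 ± 0.19, and the peptide transporter subunit Tap2 at 1.89 ± 0.18. Among 21 interferon-inducible GTPases and chemokines 7 rose (15 adjusted over the list alone), including the immunity-related GTPases Igtp at 5.62, Iigp1 at 4.66 and Irgm2 at 4.45. That list had a median of 2.79 (adjusted p = 8.4e-33, and adjusted p = 0.061 with an estimated correlation). Of 22 receptors, kinases and factors of the interferon pathway 4 rose, namely Usp18, Irf7 at 5.83 ± 0.49, Stat2 at 3.21 ± 0.17 and Irf9 at 1.95 ± 0.18, the last 3 being transcription factors that act downstream of the receptor. The median of that list was only 0.04 (adjusted p = 7.0e-05, and adjusted p = 0.20 with an estimated correlation). The receptor genes Ifnar1 and Ifnar2 stood at -0.46 ± 0.20 and 0.03 ± 0.43 and did not pass. When LP control replicate 1 was left out, the adjusted p of Irf9 was 0.055, of Tap2 0.054 and of H2-Q10 0.089.

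The remaining lists held few calls in MaSC. None of 34 cell cycle genes passed, although their median was -0.44 (adjusted p = 1.5e-07, and adjusted p = 0.65 with an estimated correlation; -0.19 without MaSC control replicate 1, adjusted p = 0.12). No p53 and cell-death gene passed over all genes and 3 did over the list alone. The camera test called that list upward (adjusted p = 0.043, and adjusted p = 0.48 with an estimated correlation), with a mean of 0.22 but a median of -0.04. It lost the call without any 1 array other than those of the LP controls (adjusted p = 0.052 to 0.13). The other 15 lists were not called, although the endothelial and mural list was without LP control replicate 1 (median 0.23, adjusted p = 0.036, and adjusted p = 0.55 with an estimated correlation). Among the markers of the populations, Krt5 and Krt14, the basal keratins, stood at -0.31 and 0.21, the basal transcription factor gene Trp63 at -0.18, the luminal keratin gene Krt8 at 0.07, and Elf5 and Kit, both high in luminal progenitors, at -0.50 and -0.81. None of these passed. Well-known targets could miss the threshold despite large values, because all groups share 1 spread per gene. Ifi27l2a stood at 8.72 (adjusted p = 0.054) and Trim30a at 7.13 (adjusted p = 0.081), above all genes that passed. Isg15, a ubiquitin-like modifier, stood at 6.70 (adjusted p = 0.075), Ifit1, which binds foreign RNA, at 7.48 (adjusted p = 0.12) and the antiviral GTPase gene Mx1 at 6.62 (adjusted p = 0.13), and without LP control replicate 1 the adjusted p of these 3 genes were 0.0071, 0.0054 and 0.011.

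The second comparison asked the same in LP cultures, where 72 genes rose with IFNα and none fell (0 falls by limma, with 1618 genes in both directions at an unadjusted p under 0.05). Gbp3 rose by 6.96 ± 0.57 (adjusted p = 0.017), Oasl2 by 6.72 ± 0.41 (adjusted p = 0.0088), Usp18 by 6.45 ± 0.40 (adjusted p = 0.0090), Bst2, which tethers budding virions to the cell, by 6.13 ± 0.28 (adjusted p = 0.0046), and Ifit3b by 5.96 ± 0.51 (adjusted p = 0.020). The lowest p among lower genes belonged to Arhgap24 at -1.47, Dipk1b at -1.80 and Olfr424 at -1.35, none of which passed (adjusted p = 0.082, 0.11 and 0.11). The count of 72 genes was 54 without LP control replicate 1, 422 (214 higher and 208 lower) without LP control replicate 2, 21 without either MaSC control array, 3 without either MaSC array with IFNα and 0 without either LP array with IFNα. The LP groups fitted alone gave 0.

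The interferon lists again held most of the response in LP. Of 53 interferon-stimulated genes 28 rose (52 adjusted over the list alone), with a median log2 change of 3.42 (camera adjusted p = 3.6e-84, and adjusted p = 0.043 with an estimated correlation). Ddx60, a helicase that senses viral RNA, rose by 5.83 ± 0.25. Of 26 MHC class I presentation genes 8 rose (19 adjusted over the list alone), with a median of 2.13 (adjusted p = 1.8e-26, and adjusted p = 0.043 with an estimated correlation, or 0.096 without LP control replicate 1). B2m rose by 3.80 ± 0.17, Psmb8, an immunoproteasome subunit, by 3.48 ± 0.37, H2-T10 by 2.84 ± 0.22 and H2-Q7 by 2.67 ± 0.28. Of 21 GTPases and chemokines 7 rose (12 adjusted over the list alone, with 3 lower), among them Igtp at 5.02, Iigp1 at 4.35 and Irgm2 at 4.20, with a list median of 1.96 (adjusted p = 1.5e-11, and adjusted p = 0.29 with an estimated correlation). Of 22 pathway genes 3 rose, Usp18, Irf7 at 4.78 ± 0.49 and Stat2 at 3.42 ± 0.17, and the list median was 0.20 (adjusted p = 0.0020, and adjusted p = 0.29 with an estimated correlation; 0.070 with the preset one without LP control replicate 2). Ifnar1 at 0.21 and Ifnar2 at 0.22 did not pass. Of 18 p53 and cell-death genes 1 rose, Tnfsf10, which encodes the death ligand TRAIL, by 2.01 ± 0.22 (adjusted p = 0.038), with a list median of 0.19 (adjusted p = 0.028, and adjusted p = 0.34 with an estimated correlation). That list call ended without LP control replicate 2 (adjusted p = 0.48) or LP IFNα replicate 2 (0.068). Cdh5, the cadherin of endothelial junctions, also rose in LP, by 3.59 ± 0.39 (adjusted p = 0.038). Without LP control replicate 1 the adjusted p was 0.086 for Cdh5, 0.15 for Tnfsf10, 0.12 for Psmb8 and 0.13 for H2-Q7.

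Apart from the p53 and cell-death list, the lists outside the interferon programme that were called in LP had no member past the threshold over all genes. None of 34 cell cycle genes passed over all genes, 18 were lower adjusted over the list alone, and their median was -0.96 (adjusted p = 1.1e-19, and adjusted p = 0.30 with an estimated correlation). That median was -0.63 without LP control replicate 1 and -0.30 with quantile normalization. The whole-lineage luminal markers had a median of 0.81 (adjusted p = 0.0041, and adjusted p = 0.45 with an estimated correlation), the luminal progenitor markers 0.62 (adjusted p = 0.017, and adjusted p = 0.51 with an estimated correlation), the milk and secretory genes 0.40 (adjusted p = 0.046, and adjusted p = 0.29 with an estimated correlation) and the leukocyte markers -0.32 (adjusted p = 8.2e-04, and adjusted p = 0.35 with an estimated correlation). When LP control replicate 1 was left out, these 4 calls ended, with medians of 0.06, 0.15, 0.11 and -0.06, and with every array scaled to the same standard deviation those of the luminal, luminal progenitor and milk lists turned to -0.24, -0.25 and -0.12. The luminal progenitor and milk calls also ended without LP IFNα replicate 1 (adjusted p = 0.31 and 0.10), and the milk call without either MaSC control array (0.084) or LP control replicate 2 (0.0503). Hypoxia and glycolysis genes, not called with all arrays, were called without LP control replicate 1 (median 0.72, adjusted p = 0.0091, and adjusted p = 0.83 with an estimated correlation). Their list mean then stood at -0.50 and -2.00 on the LP arrays with IFNα and at -1.95 on the remaining control, so the call rested on LP IFNα replicate 1. Isg15 at 6.20 (adjusted p = 0.075), Ifit1 at 7.74 (adjusted p = 0.098) and Mx1 at 5.46 (adjusted p = 0.21) did not pass. Without LP control replicate 1 these genes stood at 7.56, 9.61 and 7.07. The population markers Krt5 at -0.16, Krt14 at -0.01, Trp63 at -1.16, Krt8 at -0.02 and Kit at 1.61 did not pass either, nor did Elf5 (adjusted p = 0.77). In the fit without LP control replicate 1 Kit stood at -0.41, Trp63 at -0.61, Elf5 at 0.21 and Krt5 at 0.29.

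**Figure D2:**
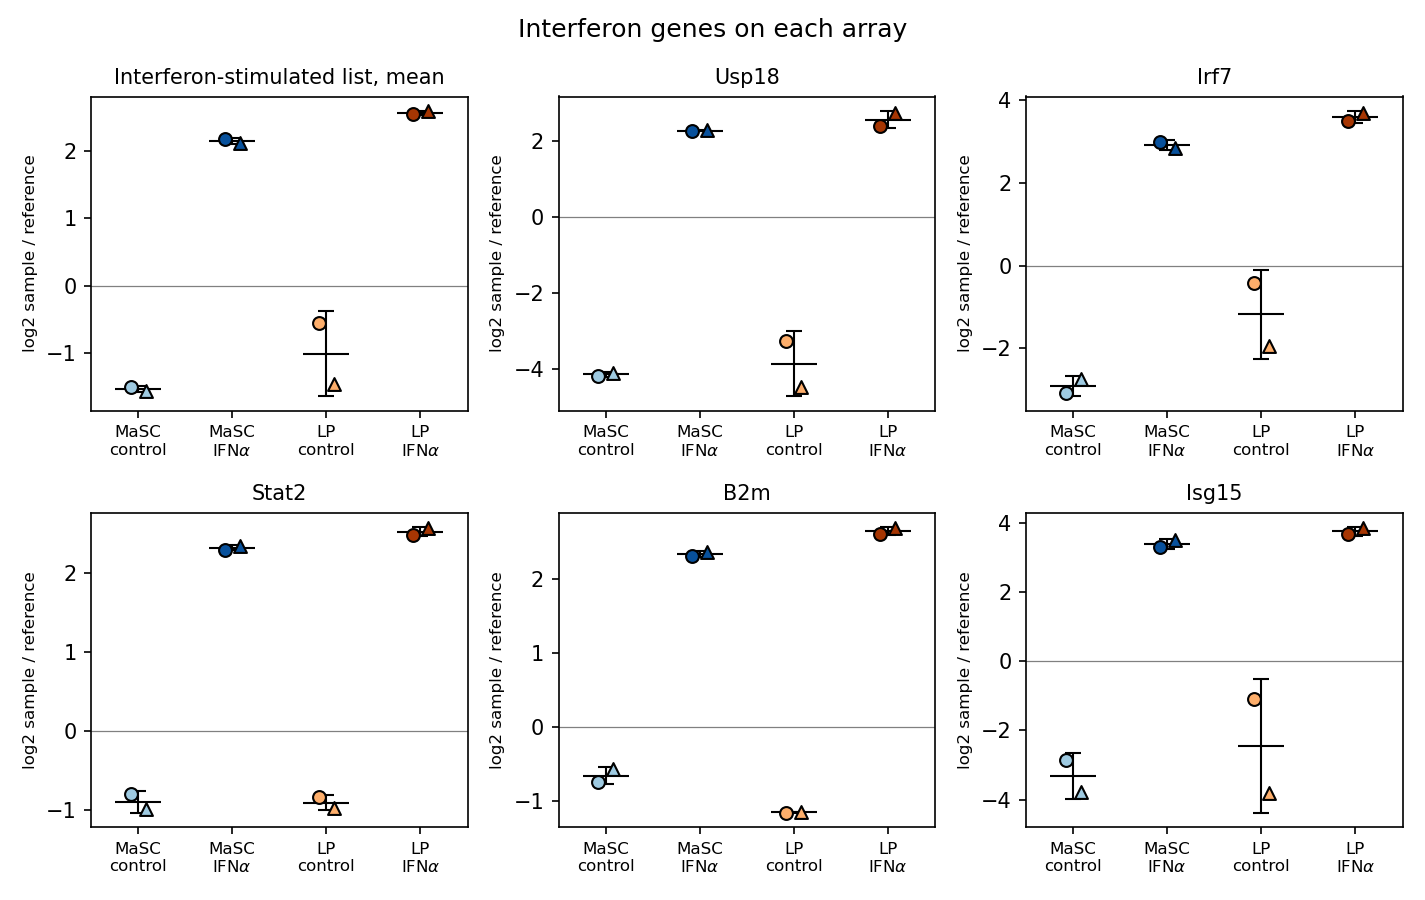
Log2 ratio of sample to reference on each of the 8 arrays for the mean of the 53 interferon-stimulated genes and for Usp18, Irf7, Stat2, B2m and Isg15. Circles are replicate 1, triangles replicate 2, horizontal bars group means and error bars standard deviations of the 2 arrays; the list mean rose from -1.54 to 2.16 in MaSC and from -1.01 to 2.57 in LP, and the LP control arrays lay apart at -0.56 and -1.46.

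The design also asks whether both populations responded alike. The interferon-stimulated genes moved by similar amounts in MaSC and LP. Their mean log2 ratio was -1.54 ± 0.05 (standard deviation, n = 2) in MaSC controls and 2.16 ± 0.04 with IFNα, against -1.01 ± 0.64 and 2.57 ± 0.03 in LP. Of the genes that rose, 45 did so in both populations, where 0.165 would be shared if the calls were independent, although both calls use the same estimate of spread. All 50 genes that rose in MaSC were higher with IFNα in LP, and 71 of the 72 that rose in LP were higher in MaSC. Across the 53 listed genes the changes in both populations correlated with Pearson r = 0.94 and Spearman rho = 0.94 (genes are not independent replicates), and the change was larger in LP for 26 of them. Over the 78 genes called in either population r was 0.86, the change was larger in LP for 49, and the median difference was -0.27. Over all 21794 genes r was 0.27 and rho 0.088.

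**Figure D3:**
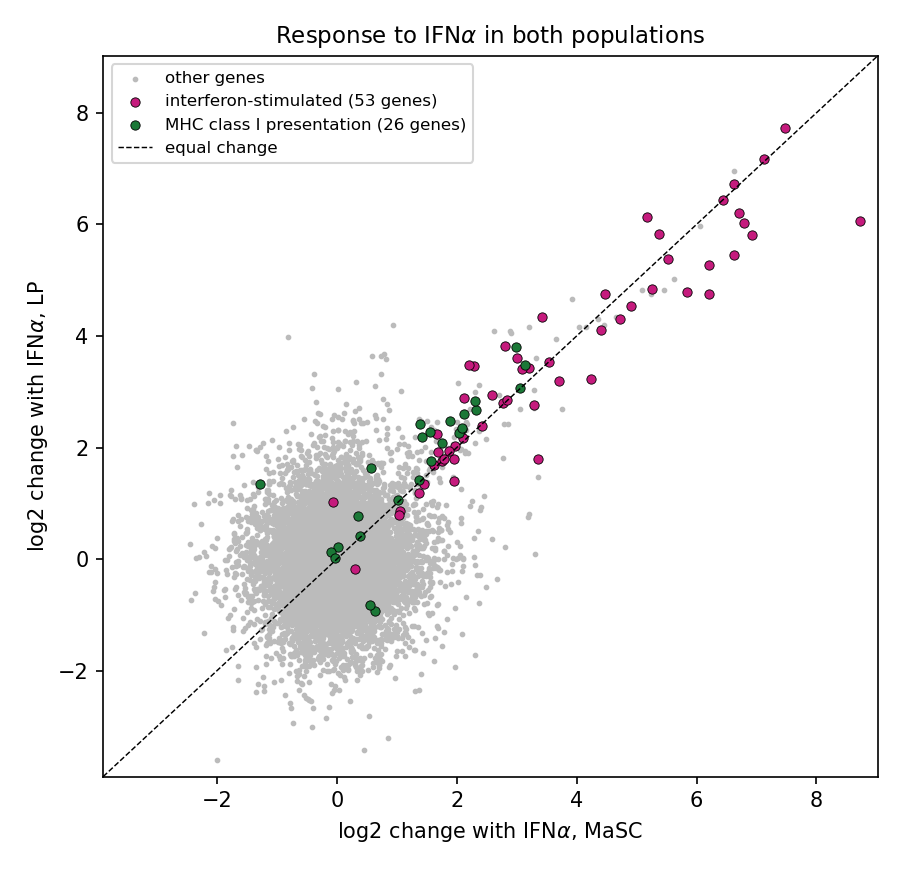
Log2 change with IFNα in MaSC (horizontal) and LP (vertical) for all 21794 genes, with the 53 interferon-stimulated genes and the 26 MHC class I presentation genes coloured and a dashed line of equal change. Most coloured genes lie along the line, with an r of 0.94 across the 53 interferon-stimulated genes.

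No gene differed in its response by the limma test of the difference itself (0 of 21794, lowest adjusted p = 0.9997). At an unadjusted p under 0.05 stood 931 genes, fewer than the share of 0.05 that chance alone would give. That count depends on the shared spread, and it does not show that the responses were alike. The differences were estimated loosely, with a median standard error of 0.44. Taken as MaSC minus LP, Isg15 stood at 0.50 with a 95% interval from -2.45 to 3.45, Ifit1 at -0.25 ± 1.60, Mx1 at 1.17 ± 1.43 and Irf7 at 1.05 ± 0.69. These values hung on LP control replicate 1, without which they were -0.86, -2.13, -0.45 and 0.29, and none passed. Cxcl9, a T-cell chemokine, stood at 2.40 ± 0.44 and Ifit2 at 1.55 ± 0.40, with higher changes in MaSC, and the class I gene H2-Q1 at -2.62 ± 0.76. Among the lowest p-values were those of Adamts6, a secreted protease gene, at 2.86 ± 0.29, and Cideb, a lipid droplet gene, at 2.29 ± 0.29. Cela3b at -2.78 ± 0.30, Gk2 at -2.14 and Olfr194 at -2.72 ± 0.37 were others, and none of these genes passed. Lcor, a ligand-dependent corepressor studied in connection with interferon signalling, stood at 0.58 ± 0.35.

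At the level of lists, the interferon-stimulated genes had a median difference of 0.00 (adjusted p = 0.70, and adjusted p = 0.89 with an estimated correlation). This value depended on the LP control arrays: without replicate 1 it was -0.29 (adjusted p = 0.026, and adjusted p = 0.98 with an estimated correlation), with 38 of 53 genes changing more in LP, and without replicate 2 it was 0.35 (adjusted p = 1.2e-04). Of the 21 lists 5 were called, and none was with an estimated correlation, where adjusted p = 0.80 for each. GTPases and chemokines had a median difference of 0.26 (adjusted p = 0.0055), cell cycle genes 0.53 (adjusted p = 1.2e-06) and leukocyte markers 0.37 (adjusted p = 0.0090), while MHC class I presentation genes had -0.29 (adjusted p = 0.017) and luminal progenitor markers -0.77 (adjusted p = 0.025). Without LP control replicate 1 these medians were -0.01, 0.20, 0.05, -0.26 and -0.22. Only the cell cycle (adjusted p = 0.026) and MHC class I lists (0.019) of the 5 were still called. The hypoxia and glycolysis list was called as well (median -0.75, adjusted p = 0.026). With an estimated correlation adjusted p = 0.98 for these 3 lists, and the hypoxia and glycolysis mean of LP IFNα replicate 1, at -0.50, stood apart from all other arrays used. The MHC class I call ended without MaSC control replicate 1 (adjusted p = 0.37), MaSC IFNα replicate 1 (0.055) or 2 (0.062), LP control replicate 2 (0.14) or LP IFNα replicate 2 (0.26). Of the 5 calls only that of the cell cycle list held with each array left out in turn. No list was called when every array was scaled to the same standard deviation, and quantile normalization turned the cell cycle median to -0.07.

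Averaged over both populations, 128 genes rose with IFNα and 1 fell. Of 53 interferon-stimulated genes 46 rose, 51 adjusted over the list alone, including Ifit1 by 7.61 ± 0.80 (adjusted p = 0.018), Ifi27l2a by 7.39 ± 0.71 and Trim30a by 7.15 ± 0.66. Oasl2 rose by 6.67 ± 0.29, Isg15 by 6.45 ± 0.60 and Mx1 by 6.04 ± 0.71. Gbp3, from the list of GTPases and chemokines, rose by 6.79 ± 0.40. Among the MHC class I presentation genes 12 of 26 rose (20 adjusted over the list alone), among them B2m by 3.40 ± 0.12, Psmb8 by 3.30 ± 0.26 and the peptide transporter subunit Tap1 by 3.07 ± 0.29. Of the GTPases and chemokines 11 of 21 rose, and of the pathway genes 4 of 22 rose, Usp18, Irf7, Stat2 and Irf9. Of the p53 and cell-death genes 2 of 18 rose, Tnfsf10 by 1.74 ± 0.16 and Mlkl, which executes necroptosis, by 1.23 ± 0.16. The only gene to fall was Rpa1, a subunit of the single-stranded DNA-binding complex of replication, by 1.08 ± 0.14 (adjusted p = 0.047), and its probes differed, at -1.86 and -0.30. Cell cycle genes did not pass over all genes, as for Cdc20, an activator of the anaphase-promoting complex, at -0.97 (adjusted p = 0.084), while 18 of 34 were lower adjusted over the list alone. The count of 129 was 81 and 73 without MaSC control replicate 1 or 2, 47 and 72 without MaSC IFNα replicate 1 or 2, 45 and 40 without LP IFNα replicate 1 or 2, and 106 and 201 without LP control replicate 1 or 2. The 201 genes held 146 higher and 55 lower. When LP control replicate 1 was left out, the adjusted p of Rpa1 was 0.14 and that of Mlkl 0.092.

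The next comparison asked how MaSC and LP controls differed. In MaSC 122 genes were higher and 9 lower, some basal genes among the higher ones. The basal and stem-cell list had a median log2 difference, MaSC minus LP, of 1.42 over 32 measured genes, of which 3 passed as higher and 17 did adjusted over the list alone. Its camera adjusted p was 4.9e-13, and adjusted p = 0.031 with an estimated correlation. Krt5 was higher by 3.85 ± 0.41 (adjusted p = 0.029), the basal cadherin gene Cdh3 by 4.83 ± 0.41 (adjusted p = 0.017) and Lgr5, a Wnt-responsive stem cell marker, by 2.18 ± 0.28 (adjusted p = 0.046), with Lgr5 probes at 0.20 and 4.16. Krt14 at 0.97 (adjusted p = 0.15) and Trp63 at 1.18 (adjusted p = 0.32), whose probes ran from -0.17 to 2.42, did not pass. No marker of the luminal lists passed over all genes, although Krt8 lay lower on both MaSC control arrays than on either LP control array. Krt8 stood at -0.93 (adjusted p = 0.40), Elf5 at 1.59 and Kit at 2.19 (adjusted p = 0.37 and 0.47; 0.59 and 0.17 without LP control replicate 1), and in MaSC controls Elf5 and Kit lay far above the reference, at 6.15 ± 0.18 and 7.89 ± 0.46 (standard deviation, n = 2). The luminal progenitor list had a median of 0.36 (adjusted p = 0.22) and the whole-lineage luminal list 0.20 (adjusted p = 0.45). The count of 131 genes was 4 without LP control replicate 1, 368 (228 higher and 140 lower) without LP control replicate 2, 0 without either MaSC control array, 44 without either MaSC array with IFNα and 35 without either LP array with IFNα, and fitting the control groups alone gave 0. Without LP control replicate 1 the adjusted p of Krt5 was 0.055, of Cdh3 0.068 and of Lgr5 0.088, and the basal list had a median of 1.70 with adjusted p = 0.11 with an estimated correlation.

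Among genes that passed, the largest single differences in controls were in Cdh5, by 6.17 ± 0.39 (adjusted p = 0.011), Prl8a9, a prolactin-family hormone gene, by 6.14 ± 0.41, Lrat, which esterifies retinol, by 5.85 ± 0.62, Cdsn, a corneodesmosome protein gene, by 5.84 ± 0.67, and Sprr1b, a cornified envelope precursor, by 5.66 ± 0.49. Lower in MaSC were Cant1, a calcium-activated nucleotidase gene, at -2.66 ± 0.30, Adamts6 at -1.58, the amino acid transporter gene Slc43a2 at -1.56, Ldlrad3 at -1.50 and Agfg2 at -1.46. Of the Wnt and Notch list 4 of 31 were higher, the Notch ligand gene Jag1 by 2.53 ± 0.22, the Notch target Heyl by 4.80 ± 0.58, Wnt10a by 2.83 ± 0.34 and Lgr5, and the list median was 0.24 (adjusted p = 0.023, and adjusted p = 0.32 with an estimated correlation), which became -0.08 with quantile normalization. That call ended without MaSC control replicate 1 (adjusted p = 0.055) or LP control replicate 1 (0.079). When LP control replicate 1 was left out, none of the genes in this paragraph passed, with adjusted p from 0.0515 for Cdh5 to 0.14 for Adamts6.

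Markers of other cell types moved with the MaSC label. Of 17 endothelial and mural markers 4 were higher in MaSC (10 adjusted over the list alone), Cdh5, the vascular sialomucin gene Emcn by 4.13 ± 0.30, Robo4 by 4.98 ± 0.51 and the VEGF receptor gene Kdr by 2.25 ± 0.26, whose probes stood at -0.07 and 4.57. The list median was 1.51 (adjusted p = 5.5e-09, and adjusted p = 0.097 with an estimated correlation), and Pecam1, which encodes CD31, stood at -0.34. Of 12 adipocyte and red-cell markers 3 were higher, the fatty acid carrier gene Fabp4 by 5.33 ± 0.37, the adipokine gene Adipoq by 4.18 ± 0.41 and the lipase gene Lpl by 1.82 ± 0.22, while the haemoglobin genes Hba-a1 and Hbb-b1 stood at -0.69 and -0.47. The list median was 1.49 (adjusted p = 5.1e-05, and adjusted p = 0.25 with an estimated correlation). Of 16 fibroblast markers 1 was higher, the proteoglycan gene Dcn by 2.43 ± 0.27, with a median of 1.53 (adjusted p = 7.0e-07, and adjusted p = 0.33 with an estimated correlation). Of 19 epithelial-mesenchymal transition genes 1 was higher, the protease gene Mmp3 by 2.34 ± 0.21, with a median of 1.43 (adjusted p = 3.1e-05, and adjusted p = 0.33 with an estimated correlation). The 23 leukocyte markers were not called (adjusted p = 0.092). Cell cycle genes, not called with all arrays, were called without LP control replicate 1 (median 0.42, adjusted p = 3.0e-04, and adjusted p = 0.75 with an estimated correlation). Without LP control replicate 1 the adjusted p of Adipoq was 0.044, of Cdh5, Emcn, Robo4 and Fabp4 0.0515, of Kdr and Mmp3 0.073, of Dcn 0.098 and of Lpl 0.11.

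A lower level of interferon genes in MaSC controls depended on LP control replicate 1. The 53 interferon-stimulated genes had a median of -0.43 (adjusted p = 7.3e-05, and adjusted p = 0.63 with an estimated correlation), but none passed. When LP control replicate 1 was left out, that median was -0.09 (adjusted p = 0.52). GTPases and chemokines had a median of -0.54 (adjusted p = 0.020, and adjusted p = 0.66 with an estimated correlation; -0.27 without that array, adjusted p = 0.61, and -0.47 without MaSC control replicate 2, adjusted p = 0.10), although their only member past the threshold, the monocyte chemokine gene Ccl2, was higher in MaSC by 2.63 ± 0.32 (adjusted p = 0.038, and 0.071 without that array). Irf7 at -1.74, Ifnar1 at -0.24 and Ifnar2 at -0.85 did not pass (-0.97, -0.39 and -0.53 without that array), nor did Lcor at -1.29 ± 0.25 (adjusted p = 0.12), with group means of -0.22 ± 0.22 in MaSC and 1.06 ± 0.33 in LP (standard deviation, n = 2).

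**Figure D4:**
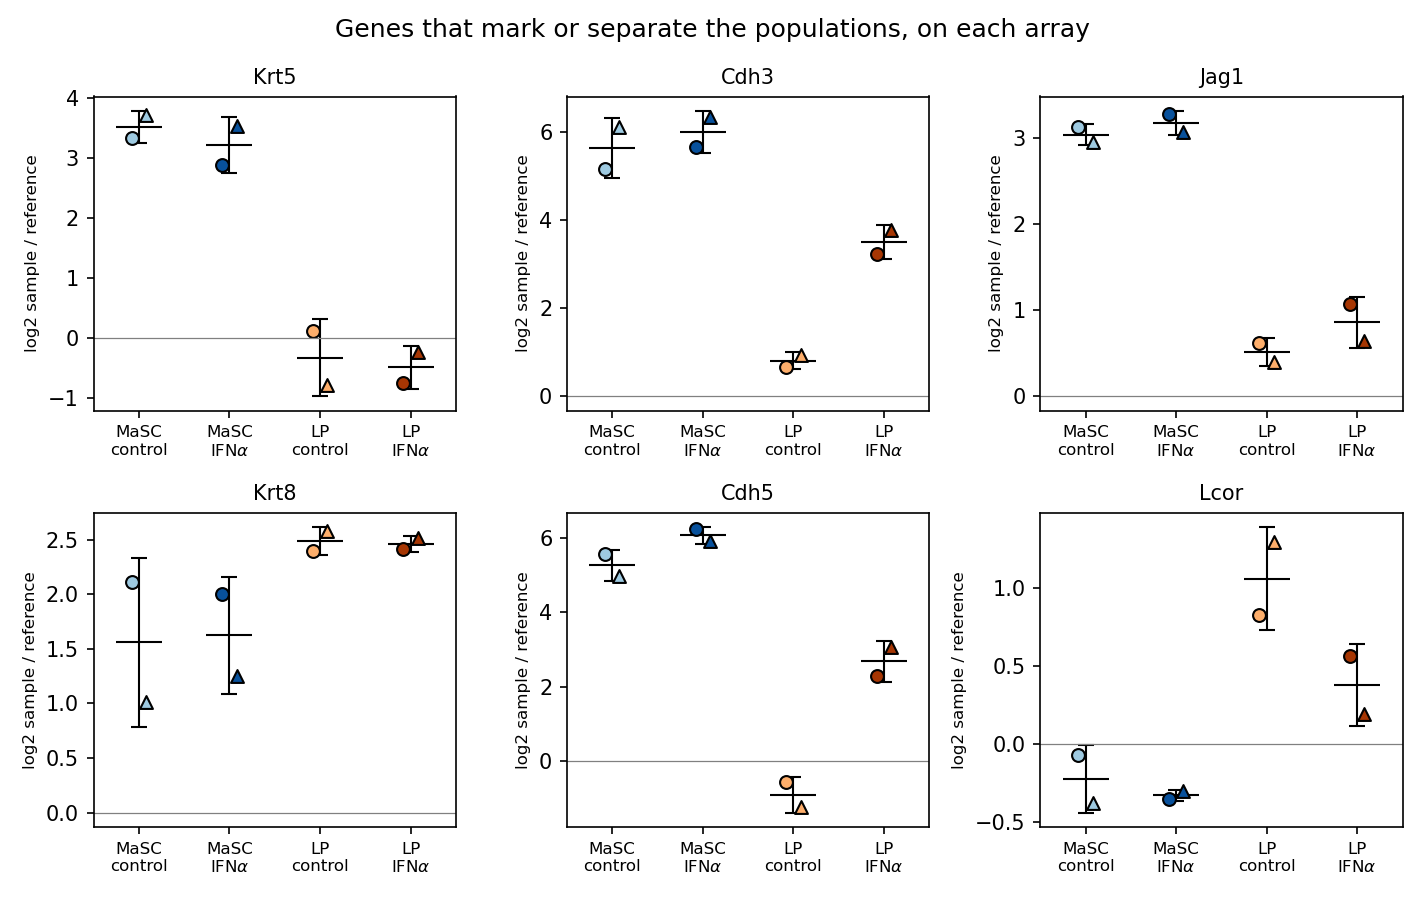
Log2 ratio of sample to reference on each of the 8 arrays for the basal genes Krt5 and Cdh3, the Notch ligand gene Jag1, the luminal keratin gene Krt8, the endothelial cadherin gene Cdh5 and Lcor. Circles are replicate 1, triangles replicate 2, horizontal bars group means and error bars standard deviations of the 2 arrays; Krt5 was higher in MaSC by 3.85 in controls and by 3.70 with IFNα, while Krt8 and Lcor did not pass.

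The last comparison placed MaSC against LP after IFNα, and it does not use the LP control arrays except for the shared spread. In MaSC 99 genes were higher and 11 lower. Defb1, an epithelial antimicrobial peptide gene, was higher by 9.03 ± 1.08 (adjusted p = 0.039), Tprg by 8.00 ± 0.82, Flg, which encodes the epidermal barrier protein filaggrin, by 6.59 ± 0.68, Cdsn by 6.45 ± 0.67 and Sprr1b by 6.10 ± 0.49. Lower were Chrna6, a nicotinic receptor subunit gene, at -2.91 ± 0.34, Cp, which encodes the copper carrier ceruloplasmin, at -2.65 ± 0.32, Apobr at -2.64, Npat, a coactivator of histone gene transcription, at -2.60 and Pnpla7 at -2.08. Of the genes higher in controls, 79 were also among the 99, where 0.554 would be shared by independent calls, and 4 of the lower genes were shared. The count of 110 genes was 165 without either LP control array, 53 without either MaSC control array and 0 without any 1 of the arrays with IFNα, and fitting the treated groups alone gave 0. Without LP control replicate 1 the adjusted p of Defb1 was 0.056, of Cp 0.053, of Apobr and Chrna6 0.051.

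Basal genes were higher in MaSC after IFNα too. The basal list had a median of 1.90 (adjusted p = 1.5e-14, and adjusted p = 0.025 with an estimated correlation, or 0.087 without LP control replicate 1), with 2 of 32 genes higher (20 adjusted over the list alone), Krt5 by 3.70 ± 0.41 (adjusted p = 0.034) and Lgals7, a keratinocyte galectin gene, by 5.27 ± 0.49. Krt14 at 1.19 (adjusted p = 0.085), Trp63 at 2.16 (adjusted p = 0.11), Krt8 at -0.84, Elf5 at -0.12 and Kit at -0.23 did not pass. Of 17 endothelial and mural markers 3 were higher (11 adjusted over the list alone), Cdh5 by 3.39 ± 0.39, the angiopoietin receptor gene Tek by 3.29 ± 0.42 and Emcn by 2.70 ± 0.30, with a median of 1.84 (adjusted p = 1.0e-11, and adjusted p = 0.060 with an estimated correlation). Of 12 adipocyte and red-cell markers 2 were higher, Fabp4 by 4.16 ± 0.37 and Lpl by 2.33 ± 0.22, with a median of 0.74 (adjusted p = 4.9e-05, and adjusted p = 0.25 with an estimated correlation). No fibroblast marker passed over all genes and 8 of 16 did over the list alone, with a median of 1.38 (adjusted p = 8.5e-08, and adjusted p = 0.40 with an estimated correlation). Mmp3, higher by 1.92 ± 0.21, was the only one of 19 epithelial-mesenchymal transition genes to pass, with a list median of 1.11 (adjusted p = 2.1e-04, and adjusted p = 0.49 with an estimated correlation). Jag1, by 2.32 ± 0.22, and Wnt10a, by 2.86 ± 0.34, were higher, and the Wnt and Notch list was not called (adjusted p = 0.16).

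Interferon and antigen-presentation genes stood slightly lower in treated MaSC than in treated LP by list. The interferon-stimulated genes had a median of -0.39 (adjusted p = 9.1e-04, and adjusted p = 0.62 with an estimated correlation) and the MHC class I presentation genes -0.50 (adjusted p = 7.2e-04, and adjusted p = 0.40 with an estimated correlation), and no member of either list passed. Bst2 at -1.60 (adjusted p = 0.086, but 0.049 without LP control replicate 1), Ifnar1 at -0.90 (adjusted p = 0.13) and Ifnar2 at -1.05 (adjusted p = 0.30) did not pass, nor did Lcor at -0.71 (adjusted p = 0.25). Cell cycle genes had a median of 0.64 (adjusted p = 3.1e-09, and adjusted p = 0.51 with an estimated correlation), with none past the threshold over all genes and 9 of 34 over the list alone. Mature luminal markers had a median of 0.76 (adjusted p = 0.026, and adjusted p = 0.51 with an estimated correlation; 0.22 and 0.48 without MaSC or LP IFNα replicate 2, adjusted p = 0.25 and 0.16), with Tbx3, a mammary patterning factor gene, higher by 2.24 ± 0.27 (adjusted p = 0.039, and 0.053 without LP control replicate 1), and hypoxia and glycolysis genes -0.69 (adjusted p = 0.031, and adjusted p = 0.80 with an estimated correlation). The hypoxia and glycolysis difference hung on LP IFNα replicate 1, without which the median was 0.06 (adjusted p = 0.94). The list mean was -0.50 on that array, -2.00 on LP IFNα replicate 2 and -2.05 and -1.84 on the MaSC arrays. Its call also ended without MaSC IFNα replicate 1 (median -0.53, adjusted p = 0.16).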

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

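The tests in this part were chosen after the results were seen, except the check for IFNα in LP control replicate 1. The gene lists taken up here are 5, those that the test of the difference between the IFNα responses (MaSC minus LP) called with a preset correlation: interferon-inducible GTPases and chemokines with a median difference of 0.26, MHC class I presentation genes with -0.29, luminal progenitor markers with -0.77, cell cycle genes with 0.53 and leukocyte markers with 0.37. With an estimated correlation adjusted p = 0.80 for each. Groups of 2 are too small for a test of single outlying samples.

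The first pattern is the narrow LP control replicate 1, whose values were drawn toward 0. A single factor for the whole array, without added noise, is argued against. Among 966 genes far from the reference in the other LP arrays, the median ratio of this array to them was 0.42. The interquartile range of that ratio was 0.446. It was 0.172 for LP control replicate 2, but that array helped choose the genes, so its narrow range is partly built in. A single factor with noise on top would also widen the range and stays open. MaSC cells in the sample as the only source are argued against too. In this array 111 low genes at like levels in both populations were higher than in replicate 2 by a median of 2.89. The same genes differed by -0.05 between MaSC control replicates. They were chosen by their mean over all other arrays, these included, so part of the shift may come from that choice. Such genes cannot show whether some MaSC cells were present beside another cause, which stays open. IFNα that reached the sample is argued against, because the interferon-stimulated genes exceeded genes matched on level by -0.0329 (interquartile range 0.62). Also open, and untested because intensities were not used here, is weak signal over background, which may draw dim genes toward 0 more than bright ones. A biological difference between the LP control samples was not tested, since the design names none.

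The second pattern is the higher endothelial and mural markers in MaSC. The narrow LP array as their source is argued against: with IFNα, where it is not used, the median was 1.84 against 1.51 in controls. Endothelial cells in the MaSC samples may account for the pattern, as a hypothesis. With IFNα 88.2% of the list (15 of 17) was higher by over 0.5. Cdh5 stood at 3.39, Emcn at 2.70 and Kdr at 1.84, the last of which did not pass (limma adjusted p = 0.060). This test was set after the list had been seen to be higher, so a high share was likely. Of the 17 genes 1 is also in another list. Against this hypothesis stood Pecam1, which encodes CD31, at 0.18 with IFNα and -0.34 in controls. CD31 is often used to remove endothelial cells in such sorts, though the labels name no such gate. Cdh5 also rose in LP with IFNα, by 3.59. Adipocyte and red-cell markers and fibroblast markers were higher in MaSC too, with medians of 0.74 and 1.38 with IFNα. In LP with IFNα 9 of the 17 genes were above the reference, against 14 in MaSC. Expression by the cultured epithelial cells therefore stays open.

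The third pattern is the list differences themselves. When the narrow array was left out 1 of the 5 lists kept at least 0.5 of its median, so that array may account for the GTPase, luminal progenitor, cell cycle and leukocyte differences, which became -0.01, -0.22, 0.20 and 0.05, although the cell cycle list was still called (adjusted p = 0.026). It does not account for the MHC class I difference, which stayed at -0.26. That difference remains open, since it was not called with an estimated correlation, with 5 of the other arrays left out singly or with arrays scaled to the same standard deviation.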

How the results depend on the processing

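Scaling every array to the same standard deviation was added after the data were seen; the other settings were planned. Counts kept within 1.5 times of the reported count are not listed, although the genes called could still change. Quantile normalization called 53 genes for IFNα in MaSC, 35 of them among the 51 reported. The replicate block called 117 between controls, 75 of them among the 131 reported. Array weights called 66 for IFNα in MaSC and kept all 51. The cause of the changes was not tested unless given. With the replicate number as a block, 12 genes passed for IFNα in MaSC (reported 51), 27 in LP (72) and 54 between the treated populations (110). Olfr194, the only fall in MaSC, lost its call with the block (adjusted p = 0.063) and with the highest probe (0.051). The labels state no shared batch behind the numbers, and deviations from group means correlated across genes at 0.31 between MaSC control and MaSC with IFNα but between -0.02 and 0.11 in the other pairs of groups. With only the compared groups in the fit 0 genes passed in each of these comparisons and in controls, where fewer samples leave 2 residual degrees of freedom. Between control populations (131) quantile normalization gave 207, scaling to the same standard deviation 213, trend and robust moderation 68 and array weights 80. Between treated populations leaving out genes of low mean gave 170 and array weights 269. With 2 arrays per group the model must give both the same weight, so array weights could not mark down LP control replicate 1 alone. No setting gave a gene for the difference of responses. Median centring moved the median of all genes between control populations from -0.01 to -0.11, so changes there are relative to that shift.

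With each array left out in turn, which leaves a group with a lone sample assumed to vary like the others, counts ran from 0 to 57 for IFNα in MaSC, 0 to 422 in LP, 0 to 368 between controls, 0 to 165 between treated populations and 40 to 201 for the average. The LP control arrays gave the upper ends. These counts do not show that the same genes were called. Part of the reported genes lost their calls at each upper end.

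An estimated correlation left 2 of 6 lists called in MaSC, 2 of 10 in LP, 0 of 5 for the difference, 1 of 8 between controls and 1 of 10 between treated populations. Leaving out genes of low mean, which removes list members, left 5 lists in LP, 0 for the difference and 6 between treated populations. For the difference, quantile normalization left 1, the highest probe 3, scaling 0, and single arrays left out 2 to 6. Between controls, single arrays left out gave 6 to 14. The interferon-stimulated list kept its rise in both populations under all settings run. Its median difference of responses ran from -0.29 to 0.35, past the threshold at both ends, and its control difference from -0.83 to -0.0900, with -0.25 after scaling (adjusted p = 0.088). With an estimated correlation its -0.43 in controls and -0.39 after IFNα had adjusted p of 0.63 and 0.62. In LP the whole-lineage luminal median turned to -0.0702 with quantile normalization and -0.24 with scaling, the luminal progenitor median to -0.25 and the milk median to -0.12 with scaling, and the cell cycle difference to -0.0740 with quantile normalization. List tests were not run for single probes, for the compared groups alone or with a minimum change. Intensities were not used here, so how far signal over background limits each value is unknown.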

Other observations

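The tests in this part were chosen after the results were seen, except the splits of the samples and the test of IFNα on the epidermal genes. Genes of the cornified envelope, the protein shell of epidermal and oral keratinocytes, were prominent among the genes higher in MaSC than in LP. From a list of 52 such genes written after the 19 that passed had been seen among the genes called, 51 were measured. In controls the median difference was 2.70, with 42 genes (82.4%) higher by over 0.5 and 19 past the threshold. With IFNα the median was 2.25, with 18 past the threshold. Because the list was chosen from this pattern, no p is given for it as a whole. The 32 members that had not passed, which leaves out the highest ones, had a median of 1.27 in controls (23 higher by over 0.5, limma camera p = 4.5e-10, and p = 0.071 with an estimated correlation) and 0.64 with IFNα (18 higher by over 0.5, p = 3.0e-06, and p = 0.14 with an estimated correlation). These 32 members were also written down after the pattern was seen, so their p are not independent support. The counts of passing genes depended on single arrays. In controls 2 genes passed without LP control replicate 1 (median 2.14), 0 without either MaSC control array, 7 without either LP array with IFNα and 8 without either MaSC array with IFNα. With IFNα 0 passed without any 1 of the arrays with IFNα and 12 without either MaSC control array, while the list median stayed between 1.71 and 2.50. Examples in controls were the desmosomal cadherin gene Dsg1a at 5.63, the envelope precursor Ivl at 3.43, the protease gene Klk5 at 4.61 and Krtdap at 4.19, while Krt1, Krt10 and Lor, abundant in skin, stood at 1.72, 1.57 and 2.46 and did not pass.

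A candidate explanation is a squamous programme in the MaSC cultures, as a hypothesis. Its test asked whether at least 80% of the list was higher by over 0.5 with IFNα, and 72.5% was (37 of 51), which decides neither way. That IFNα lowered these genes is argued against, with a median change of -0.0142 in MaSC and 0.06 in LP. Whether keratinocytes entered the culture or mammary cells took on these genes was not tested, and the share includes the 19 genes seen before the list was written.

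Hypoxia and glycolysis genes stood apart on LP IFNα replicate 1 and lay at a similar level on LP control replicate 1. The mean log2 ratio of that list was -0.50 on that array, against -2.00 on LP IFNα replicate 2, -1.95 on LP control replicate 2 and -2.05 to -1.72 on the MaSC arrays. On the narrow LP control replicate 1 it was -0.55. Other low lists lay nearer 0 on that array too, by differing amounts. Leukocyte markers stood at -0.72 against -1.96 on LP control replicate 2. Fibroblast markers stood at -1.42 against -2.42, and epithelial-mesenchymal transition genes at -1.61 against -2.22. Whether LP control replicate 1 shared the higher level or was only drawn toward 0 was not tested.

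Probes with no gene symbol, 24936 with values on all arrays, were tested on their own. None passed for IFNα in MaSC or LP by limma (0 in each), and 3 passed as higher in MaSC controls. For IFNα 1275 and 1395 probes had an unadjusted p under 0.05, not far above the share of 0.05 that chance alone would give.

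For the average response, the 35 ways to split the 8 samples into groups of 4 were compared by the genes they called. The treatment split called 137 genes and the split by population 1492, so 2 of the 35 splits gave as many as the treatment. All other splits called 0. The share of all splits cannot decide on chance. It holds only the treatment split itself and the population split, a structure of the samples that the design names.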
